A study of Homo sapiens with 4 samples.

How the data were processed

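Total RNA from 4 cultures of human cells was labelled with biotin and hybridised to 1-colour Affymetrix GeneChip expression arrays, 1 array per culture. Per the labels, 2 arrays held RNA of the parental MCF-7 line and 2 held RNA of MCF-7/ADR, a subline obtained by multi-step selection in doxorubicin. Per the series' design text, the 2 cultures of each group were biological replicates grown and harvested independently. That text also names the resistant replicates with differing amounts in ng, without saying what the amounts refer to, so it is not known whether both were kept under the same selection. Per the labels' protocols, RNA came from cells that remained attached after medium and detached cells had been removed. The p-values rest on the spread between the 2 cultures within each group. The labels name only 1 resistant subline, so the p-values do not cover the spread between independent selections.

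The deposited values are on a log2 scale and were made by the authors with RMA, per the submitters' processing notes. RMA (robust multi-array average) combines background correction, normalisation between arrays and a summary of the probes of each probe set. The RMA version and the software are not given in the sources used here. That the scale is log2 was read from the values, which ran from 3.05 to 13.51 over the 4 arrays. The median log2 value per array was 5.39, 5.40, 5.47 and 5.52 for parental 1, parental 2, resistant 1 and resistant 2. The SD over probe sets was 2.11, 2.11, 2.09 and 1.96 in the same order, so the distributions were close but not equal. No detection calls were used, so a low value does not show that a transcript was absent. Folds measured against values near the low end are compressed on such arrays. The number of arrays limits the precision.

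The table held 22277 probe sets, of which 62 were control probe sets and stayed out of the gene tests. Probe sets were named through GEO's platform annotation, which listed 20113 of them. After leaving out the controls, 19064 had 1 gene symbol, 1043 had several and 2108 had none here. Symbols were updated by Entrez identifier through a RefSeq gene table of assembly GRCh38.p14, in which the identifiers of 12 probe sets were not found. That table was used for names and for the order of genes along chromosomes, and no coordinates were taken from it. In the gene lists, 3 symbols were matched through synonyms. Each of the 11963 genes was represented by its probe set with the highest mean over the 4 arrays, taken from probe sets with 1 symbol. Of 4310 genes with more than 1 probe set, 7 had probe sets called in opposite directions. Genes of families with near-identical members (AKR1C1 and AKR1C2, HLA-B, metallothioneins, tubulins, pregnancy-specific glycoproteins) are uncertain, because probes can bind transcripts of several members.

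Resistant and parental arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, group as the only term, all arrays weighted equally). All p-values are two-sided, and genes were called at a Benjamini-Hochberg adjusted p under 0.05 over the 11963 genes. Positive log2 fold changes mean higher in the resistant subline. The standard error (SE) is that of the moderated fit, with a prior SD of 0.187 on 2.46 degrees of freedom. Gene lists with at least 5 measured members were tested with camera at a preset inter-gene correlation of 0.01, and p-values were adjusted over the 28 lists. For each list the number of members called was also counted with p-values adjusted over the list alone. Camera was repeated with a correlation estimated per list, which rests on few residual degrees of freedom here. The 3' and 5' control probe sets of ACTB and GAPDH were compared by an exact permutation test. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

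The groups, tests, lists and most alternatives were fixed before the data were examined. Named genes were the 10 largest rises and the 10 largest falls among called genes whose groups did not overlap, 16 genes of interest fixed by name, and up to 4 called members of each list with the largest change. Of the 16, CASP3 was not measured by a probe set with 1 symbol. The lists covered ABC transporters, the neighbourhood of ABCB1, xenobiotic metabolism, DNA repair, p53 targets, apoptosis, stem cell markers, pluripotency factors, the Notch, Wnt and Hedgehog pathways, mesenchymal, epithelial, luminal and basal genes, oestrogen receptor targets, Müllerian, fibroblast, endothelial and haematopoietic markers, extracellular matrix, interferon, NF-kB, growth factors, proliferation, genes amplified in MCF-7, hypoxia and ribosomal proteins.

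The procedure was tested on simulated data for the 11963 genes, with 200 genes changed. Of 50 genes changed by each size, 1 was recovered at a log2 change of 1, 33 at 2, 47 at 4 and 49 at 6. Among 135 genes called, 5 had not been changed (3.70%). No gene was called when none had been changed. A list with shifted members was called, and none of 28 lists was called when none had been shifted. The simulation drew genes independently and gave both groups the same variance. In the data, the median within-group SD was 0.085 in the parental and 0.229 in the resistant group, and genes of a list may move together. These simulated error rates therefore do not carry over to the data.

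The alternatives were the mean over a gene's probe sets, all probe sets tested separately, probe sets ending in _s_at or _x_at left out, genes with a group mean of at least 6 only, a further quantile normalisation, centring of each array on its median, eBayes with trend and robust options, a minimum absolute log2 fold change of 1, an adjusted p under 0.01, the replicate number as a block, each array left out in turn, and for lists an estimated correlation and the fry test. The filter at 6 kept a gene whose mean reached 6 in either group, so it depends on the values compared. With an array left out, the lone array of its group was assumed to vary like the other group. Array weights estimated by limma were added after the data had been seen. Probe sets with no or several symbols were counted but not named, and scanner files were not used here.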

Results

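The comparison asked how the transcriptome of MCF-7 cells selected in steps with doxorubicin differed from that of parental MCF-7 cells. MCF-7 is an oestrogen receptor-positive line of luminal breast carcinoma, and doxorubicin is an anthracycline that poisons topoisomerase II. According to the series title, the study was concerned with prolonged drug selection and characteristics of cancer stem cells. Expression was measured on 4 arrays, 2 per group. Over the 11963 genes, Pearson's r was 0.996 between the parental arrays and 0.966 between the resistant arrays, and it ran from 0.811 to 0.851 between arrays of different groups. These correlations are across genes, which are not independent replicates. The parental arrays differed by more than 1 log2 unit for 1 gene and the resistant arrays for 975 genes. The median within-group SD was 0.085 in the parental group and 0.229 in the resistant group.

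Transcripts of a multidrug transporter and of mesenchymal genes were higher in the resistant cells, and luminal and epithelial transcripts were lower. ABCB1, which encodes the drug efflux pump P-glycoprotein, rose from 3.85 ± 0.04 to 11.44 ± 0.05 log2 units (mean ± SD, n = 2 per group). This was a log2 change of 7.58 (SE 0.14, limma adjusted p = 0.000399), or 192-fold. MMP1, an interstitial collagenase, rose by 7.66, the intermediate filament gene VIM by 7.63 and the lactate dehydrogenase subunit gene LDHB by 7.56. The other genes among the 10 largest rises were NNMT (7.02), FSTL1 (6.85), CCN2 (6.78), GPX1 (6.69), UCHL1 (6.56) and AKAP12 (6.44). AGR2, a luminal secretory pathway gene, had the largest fall, from 12.33 to 4.00 (log2 change -8.33, SE 0.21, limma adjusted p = 0.000446). UBB, a polyubiquitin gene, changed by -8.24, the oestrogen-induced gene TFF1 by -8.21, E-cadherin (CDH1) by -8.17 and keratin 19 (KRT19) by -8.09. S100P (-7.05), ESR1 (-6.98), GLUL (-6.81), SLC6A14 (-6.75) and LPCAT1 (-6.61) completed the 10 largest falls.

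In all, 1720 genes were higher and 1769 lower in the resistant subline, together 29.2% of those tested. Of these, 94 were higher and 78 lower by at least 16-fold. The counts changed with each array left out. They were 180 higher and 116 lower without parental replicate 1, 168 and 111 without parental replicate 2, 4236 and 3360 without resistant replicate 1, and 2951 and 2692 without resistant replicate 2. With an array left out, the spread comes mostly from the intact pair, which is wide for the resistant and narrow for the parental arrays. By construction, calls therefore tend to be lost without a parental array and kept without a resistant one. This holds for the named genes below too, so these numbers do not show reliance on a given array. None of the 3489 calls changed sign with any 1 array left out. Of the 113 named genes that were called, 56, among them the 20 with the largest rises and falls, were called without either parental array, and 57 lost their call without at least 1 of them. The control probe sets also differed between the groups. The log2 3' minus 5' signal of ACTB was 0.75 and 0.73 on the parental arrays and -0.02 and -0.16 on the resistant arrays (difference -0.83, exact permutation p = 0.333, the smallest that 2 against 2 arrays allow). For GAPDH the difference was -0.09 (exact permutation p = 0.667). The 18 hybridisation spike probe sets were all lower on the resistant arrays (median difference -0.74). The 27 B. subtilis control probe sets went the other way, with 26 higher and 1 lower (median difference 0.17).

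**Figure D1:**
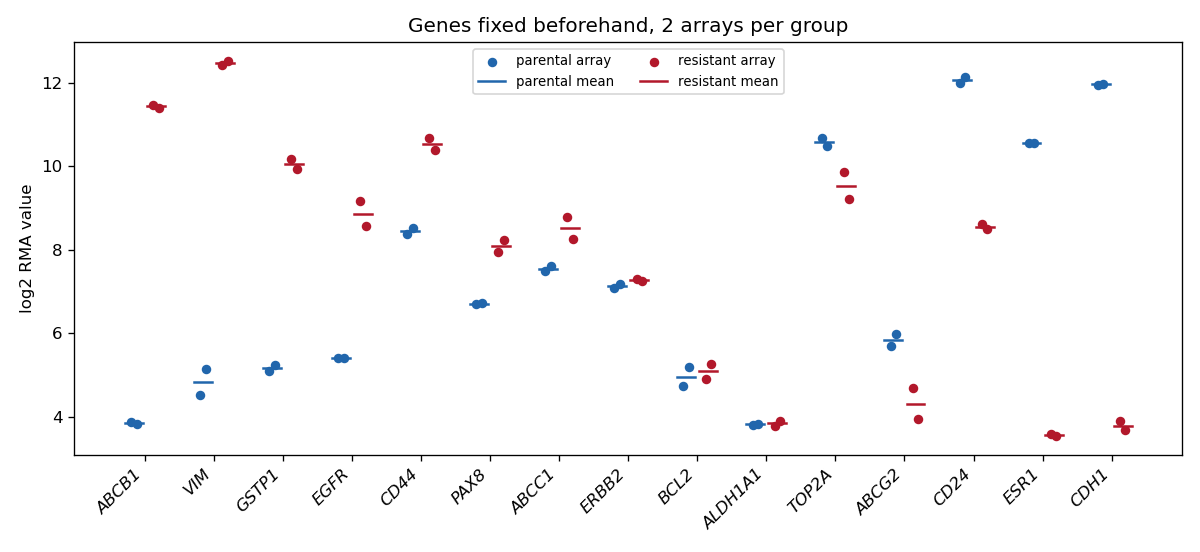
Log2 RMA values (vertical axis) of 15 genes fixed beforehand, with 1 point per array, the mean of each group as a bar, and parental arrays in blue and resistant arrays in red. Means rose from 3.85 to 11.44 for ABCB1 and from 4.83 to 12.47 for VIM. They fell from 11.96 to 3.78 for CDH1 and from 10.55 to 3.57 for ESR1, and the groups of BCL2 and ALDH1A1 overlapped.

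Beside ABCB1, drug efflux transporters moved both ways. Of 13 measured genes of this list, ABCB1 included, 5 rose, 2 fell and 6 did not pass the test, and 5 and 3 passed when adjusted over the list alone. ABCC4 rose by 1.11 and ABCC1, which encodes the transporter MRP1, by 0.96 (SE 0.23, limma adjusted p = 0.0399). The ABCC1 call ended when arrays were centred on their medians (adjusted p = 0.0594) or the replicate number was a block (0.0582), and that of ABCC4 when arrays were centred (0.0521). ABCG2, the breast cancer resistance protein gene, changed by -1.53 (SE 0.30, limma adjusted p = 0.0250) and ABCC3 by -1.51. Without resistant replicate 1 the ABCC3 value was -1.004. When all probe sets were tested separately, this ABCC3 probe set did not pass (adjusted p = 0.0553), while its other one fell by 0.997 (0.0385). The list as a set did not pass against other genes (camera adjusted p = 0.377), but passed upward in the directional fry test (adjusted p = 0.00286). Among 17 measured genes listed for the region around ABCB1 on chromosome 7, 4 rose, 4 fell and 9 did not pass (5 and 4 adjusted over the list alone, camera adjusted p = 0.619). PCLO (2.92), STEAP1 (2.56) and SEMA3D (2.00) rose and SLC25A40 fell by 1.90. The first 3 are not among the 5 measured genes on each side of ABCB1. Of those nearest genes, only SRI (1.27) was higher, and 3 were lower, SLC25A40 included. The SLC25A40 call ended without probe sets ending in _s_at or _x_at (adjusted p = 0.0501) and when all probe sets were tested separately (0.0511), and its value was -1.25 without resistant replicate 2.

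Genes of glutathione and xenobiotic metabolism moved both ways. Of 28 measured, 9 rose, 6 fell and 13 did not pass (10 and 8 adjusted over the list alone, camera adjusted p = 0.979). The peroxidase genes GPX1 (6.69) and GPX3 (3.51) rose, as did the glutathione transferase gene GSTP1, from 5.17 ± 0.09 to 10.06 ± 0.17 (SD, n = 2). CYP1B1, a cytochrome P450 gene, changed by -3.91. The list of topoisomerases and double-strand break repair was lower as a set, with 0 of 25 measured genes higher, 10 lower and 15 not passing (3 and 12 adjusted over the list alone, median -0.40, camera adjusted p = 0.0350, adjusted p = 0.767 with an estimated correlation). Among the lower genes, RAD51C (-1.30) is also on the list of genes amplified in MCF-7. TOP2B changed by -1.83, BARD1 by -1.79, NBN by -1.51 and BRCA1 by -1.43. TOP2A, the other gene for a doxorubicin target, changed by -1.05 (SE 0.27, limma adjusted p = 0.0482). When all probe sets were tested separately, this TOP2A probe set did not pass (0.0570), while its other one fell by 1.49 (0.0248). The median was -0.72 without resistant replicate 1. The set call ended without resistant replicate 2 (adjusted p = 0.133), among genes with a group mean of at least 6 (0.0992, with 3 of 20 higher, 12 lower and a median of -0.96) and in the directional fry test (0.121). Without probe sets ending in _s_at or _x_at it also ended, and the median turned to 0.04 (adjusted p = 0.835).

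Among 22 measured p53 targets, 2 rose, 8 fell and 12 did not pass, with equal numbers adjusted over the list alone (median -0.43, camera adjusted p = 0.0400, adjusted p = 0.700 with an estimated correlation). GDF15 changed by -4.55 and the phosphatase gene PPM1D by -3.19, while TP53I3 (3.61) and GADD45A (3.10) rose. PPM1D is also on the list of genes amplified in MCF-7, which was lower as a set. The GDF15 value rests on a probe set ending in _x_at, and the remaining probe set gave 0.16. That remaining probe set read low in both groups (means 4.32 parental and 4.48 resistant), so it cannot decide. The set call also ended in camera under 7 other settings, with adjusted p from 0.0518 to 0.143, the highest of them without resistant replicate 2, and in the directional fry test (adjusted p = 0.0522). Of 28 apoptosis regulators, 5 rose, 3 fell and 20 did not pass (5 and 3 adjusted over the list alone, camera adjusted p = 0.472). CASP4 (2.23), BIRC5 (1.87) and BAD (1.65) rose and FADD changed by -1.65. The CASP4 call ended without probe sets ending in _s_at or _x_at (0.57, adjusted p = 0.107). The probe set then used read low in both groups (means 3.69 parental and 4.26 resistant). BCL2 gave 0.12 (SE 0.25, limma adjusted p = 0.756), but 1 of its 4 probe sets fell by 1.07 when all probe sets were tested separately.

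Of 21 measured stem cell markers, 7 rose, 4 fell and 10 did not pass (8 and 5 adjusted over the list alone, median 0.08). As a set they did not pass over all genes (camera adjusted p = 0.400), but did among genes with a group mean of at least 6, where 8 of 13 rose and 3 fell (median 1.06, camera adjusted p = 0.0468, and 0.198 to 0.590 in the other settings with the preset correlation). That filter keeps genes high in either group, so it depends on the values compared, and the pass is not separate support. The median over all measured markers was -0.030 without resistant replicate 2 and 0.16 without resistant replicate 1. CD44, a hyaluronan receptor, rose from 8.45 ± 0.10 to 10.53 ± 0.20 (SD, n = 2), a log2 change of 2.08, and CD24 fell from 12.05 to 8.55 (log2 change -3.50). The counts and the set test treat a rise alike for every marker, CD24 included. They therefore do not tell whether the cells were more or less stem-like. ANPEP (3.17) and PROCR (2.91) rose and EPCAM changed by -4.50. ALDH1A1 was near the low end in both groups (3.82 and 3.84, log2 change 0.02, limma adjusted p = 0.931). Of 19 pluripotency and self-renewal factors, 2 rose, 4 fell and 13 did not pass (2 and 4 adjusted over the list alone, camera adjusted p = 0.979). ID2 changed by -5.88, KLF4 by -5.16 and SOX4 by -2.24, and the cytokine receptor gene IL6ST rose by 2.55. The median of this list was 0.06 and its mean -0.34, camera's direction was up, and the directional fry test passed downward (adjusted p = 0.0282). Its median was 0.12 with either parental array left out.

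Among 18 Notch pathway genes, 2 rose, 3 fell and 13 did not pass, with equal numbers adjusted over the list alone (median 0.33, mean -0.03, camera direction up, adjusted p = 0.697). The Notch median was 0.066 without resistant replicate 2 and 0.078 among genes with a group mean of at least 6. JAG2 (1.41) and NOTCH2 (1.34) rose, and HEY2 changed by -3.79, HES1 by -2.09 and NOTCH3 by -0.83. Without probe sets ending in _s_at or _x_at HES1 gave 0.13, from a probe set low in both groups (means 4.12 parental and 4.25 resistant). With probe sets averaged NOTCH3 gave -0.34 (adjusted p = 0.203). Of 33 Wnt pathway genes, 3 rose, 8 fell and 22 did not pass, with equal numbers adjusted over the list alone (median 0.15, mean 0.10, camera direction down, adjusted p = 0.904). The Wnt median was 0.062 without resistant replicate 2 and -0.63 among genes with a group mean of at least 6. DKK3 (6.31), the ligand gene WNT5A (3.57) and the receptor gene FZD2 (3.43) rose and FZD1 changed by -2.55. DKK3 gave 0.33 (adjusted p = 0.212) without probe sets ending in _s_at or _x_at. The probe set then used read low in both groups (means 3.63 parental and 3.96 resistant). In the Hedgehog pathway, GAS1 (1.21) was the only one of 10 measured genes to rise and none fell, also when adjusted over the list alone (camera adjusted p = 0.343).

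Mesenchymal genes rose together. Of 35 measured, 24 rose, 1 fell and 10 did not pass (27 and 1 adjusted over the list alone), with a median of 2.95 (camera adjusted p = 2.31e-11, adjusted p = 0.388 with an estimated correlation). Beside VIM and CCN2, the actin-binding caldesmon gene CALD1 rose by 6.20 and the matrix glycoprotein gene SPARC by 6.16. Extracellular matrix and integrin genes followed, with 19 of 37 higher, 1 lower and 17 not passing (21 and 1 adjusted over the list alone, median 1.11, camera adjusted p = 1.32e-06, adjusted p = 0.250 with an estimated correlation). Beside MMP1, the collagen genes COL1A1 (5.44) and COL4A2 (5.18) and the laminin gene LAMB1 (5.13) rose. The median of the matrix list was 2.16 among genes with a group mean of at least 6 and 0.67 without probe sets ending in _s_at or _x_at.

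Epithelial junction genes moved the other way. Of 28 measured, 2 rose, 19 fell and 7 did not pass (2 and 21 adjusted over the list alone, median -1.79, camera adjusted p = 6.65e-08, adjusted p = 0.250 with an estimated correlation). CDH1 fell from 11.96 ± 0.02 to 3.78 ± 0.15 (SD, n = 2), the splicing regulator gene ESRP1 changed by -5.43, EPCAM by -4.50 and RAB25 by -4.40.

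Luminal and oestrogen-responsive genes fell together. Of 27 luminal breast genes, 1 rose, 20 fell and 6 did not pass (2 and 21 adjusted over the list alone, median -2.92, camera adjusted p = 1.10e-10, adjusted p = 0.250 with an estimated correlation). ESR1, the gene of oestrogen receptor alpha, fell from 10.55 to 3.57 (log2 change -6.98, SE 0.14, limma adjusted p = 0.000399), and AGR2, TFF1 and KRT19 were among the largest falls. Of 25 oestrogen receptor targets, 0 rose, 20 fell and 5 did not pass (0 and 21 adjusted over the list alone, median -2.72, camera adjusted p = 6.07e-12, adjusted p = 0.280 with an estimated correlation). GREB1 changed by -6.48, MYB by -5.35 and the insulin receptor substrate gene IRS1 by -4.56. Basal breast markers were higher as a set, with 7 of 16 higher, 2 lower and 7 not passing, with equal numbers adjusted over the list alone (median 0.63, camera adjusted p = 0.0494, adjusted p = 0.452 with an estimated correlation). CRYAB (4.11), EGFR (3.46), S100A2 (3.12) and MYLK (2.18) rose. That set call ended under 4 other settings (adjusted p from 0.0559 to 0.179), among them without resistant replicate 2 (0.133, median 0.34). The median ran from 0.26 without probe sets ending in _s_at or _x_at to 1.26 among genes with a group mean of at least 6. EGFR gave 0.07 without probe sets ending in _s_at or _x_at (adjusted p = 0.826), and 4 of its 6 probe sets were higher. The probe set behind the 0.07 read low in both groups (means 4.66 parental and 4.72 resistant).

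**Figure D2:**
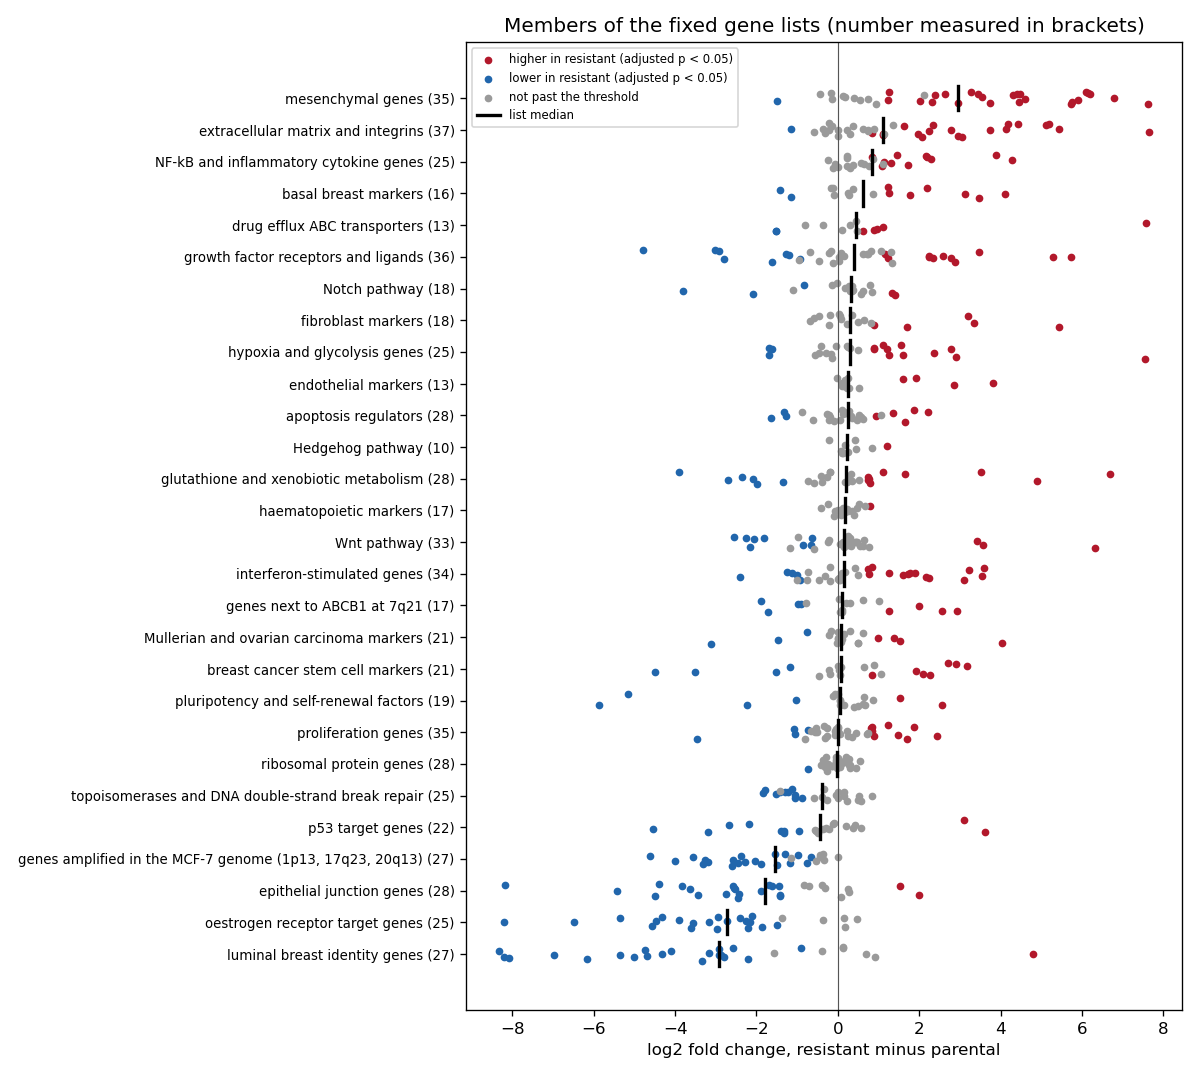
Log2 fold change (horizontal axis, resistant minus parental) of each measured member of the 28 gene lists, 1 point per gene, with the list median as a black bar and called genes in red (higher) or blue (lower). The medians run from -2.92 for luminal breast genes to 2.95 for mesenchymal genes.

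Markers of other cell types changed in part. Of 21 Müllerian and ovarian carcinoma markers, 4 rose, 3 fell and 14 did not pass, with equal numbers adjusted over the list alone (median 0.08, camera adjusted p = 0.695). The median was 0.23 without resistant replicate 1 and -0.053 without resistant replicate 2. MSLN (4.03), WFDC2 (1.53) and the transcription factor gene PAX8 (1.38, SE 0.17, limma adjusted p = 0.00700, 5 of 8 probe sets higher) rose, and MEIS1 changed by -3.12 and KLK6 by -1.47. Among 18 fibroblast markers 5 rose, 0 fell and 13 did not pass, also when adjusted over the list alone (camera adjusted p = 0.140). Without resistant replicate 1, 10 were higher and the set passed (camera adjusted p = 0.0370, and 0.0864 to 0.685 in the other settings with the preset correlation). The 5 were COL1A1, LUM (3.34), FBN1 (3.20), FBLN1 (1.71) and TCF21 (0.88). The TCF21 call ended with the replicate number as a block (adjusted p = 0.0582). Of 13 endothelial markers 4 rose, 0 fell and 9 did not pass, also when adjusted over the list alone (median 0.26, camera adjusted p = 0.0250, adjusted p = 0.700 with an estimated correlation). They were ICAM2 (3.82), TIE1 (2.85), ENG (1.93) and EGFL7 (1.60), and the set call ended under 3 other settings (adjusted p from 0.0564 to 0.232), among them without resistant replicate 2 (0.133, median 0.14). Without resistant replicate 1 the endothelial median was 0.45. The B. subtilis control probe sets, at the low end, were also higher on the resistant arrays (median difference 0.17). Medians as small as those of these marker lists were not separated from that shift. Among 17 haematopoietic markers, LAPTM5 (0.80, adjusted p = 0.0399) was higher, none was lower and 16 did not pass (0 and 0 adjusted over the list alone, camera adjusted p = 0.527). The LAPTM5 call ended under 6 other settings (adjusted p from 0.0519 to 0.337), among them without parental replicate 1 (0.337) and without parental replicate 2 (0.182).

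Of 25 NF-kB and inflammatory cytokine genes, 11 rose, 0 fell and 14 did not pass (12 and 0 adjusted over the list alone, median 0.85, camera adjusted p = 0.000328, adjusted p = 0.407 with an estimated correlation). ICAM1 (4.29), IL18 (3.89), CXCL8 (2.30) and IL6 (2.19) had the largest changes. The median was 1.73 among genes with a group mean of at least 6. Of 34 interferon-stimulated genes, 14 rose, 5 fell and 15 did not pass (14 and 6 adjusted over the list alone, camera adjusted p = 0.149). Among genes with a group mean of at least 6 this list passed as a set, with 11 of 20 higher and 4 lower (median 1.00, camera adjusted p = 0.0468, and 0.0863 to 0.983 in the other settings with the preset correlation). The filter keeps genes high in either group, so this pass too depends on the values compared. The immunoproteasome genes PSMB9 (3.59) and PSMB8 (3.23), BST2 (3.54) and HLA-B (3.09) rose. Of 36 growth factor receptors and ligands, 11 rose, 8 fell and 17 did not pass (16 and 9 adjusted over the list alone, camera adjusted p = 0.377). The receptor kinase gene AXL (5.73), the ligand gene PDGFC (5.29) and EGFR rose and BMP7 changed by -4.80. ERBB2 gave 0.15 (SE 0.14, limma adjusted p = 0.481).

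Proliferation genes had a median of 0.00. Over the arrays left out it ran from -0.075 without resistant replicate 1 to 0.15 without resistant replicate 2. It was -0.094 with each array centred on its median. Of 35 measured, 9 rose, 4 fell and 22 did not pass (10 and 6 adjusted over the list alone, camera adjusted p = 0.697). CDC20 (2.43), BIRC5 (1.87) and CCNE1 (1.71) rose and CCNE2 changed by -3.47. Of 25 hypoxia and glycolysis genes, 11 rose, 3 fell and 11 did not pass (12 and 5 adjusted over the list alone, camera adjusted p = 0.106). This list passed as a set after a further quantile normalisation (12 higher, 3 lower, camera adjusted p = 0.0454, and 0.0523 to 0.496 in the other settings with the preset correlation). LDHB (7.56), ENO2 (2.90), ADM (2.78) and the glucose transporter gene SLC2A3 (2.37) rose. Of 28 ribosomal protein genes, taken as a reference, only RPL24 passed (-0.73, adjusted p = 0.0291), none rose and 27 did not pass (0 and 0 adjusted over the list alone, median -0.03, camera adjusted p = 0.697). The RPL24 call ended with the replicate number as a block (adjusted p = 0.0594), and the list median turned to 0.016 after a further quantile normalisation and to 0.010 without parental replicate 2.

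Genes known to be amplified in the MCF-7 genome, on chromosomes 1, 17 and 20, were lower in the resistant subline. Of 27 measured, 0 rose, 20 fell and 7 did not pass (0 and 23 adjusted over the list alone, median -1.54, camera adjusted p = 3.48e-11, adjusted p = 0.407 with an estimated correlation). The helicase gene BRIP1 changed by -4.60, BCAS3 by -3.99, TBX2 by -3.55 and TUBD1 by -3.31. Without probe sets ending in _s_at or _x_at the median was -0.87. The 12 measured genes on chromosome 17 had a median of -2.89 and the 13 on chromosome 20 a median of -0.98. On chromosome 1 only 2 were measured, SIKE1 (-1.54), which was called, and AMPD1 (-0.37, limma adjusted p = 0.334), which was not.

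**Figure D3:**
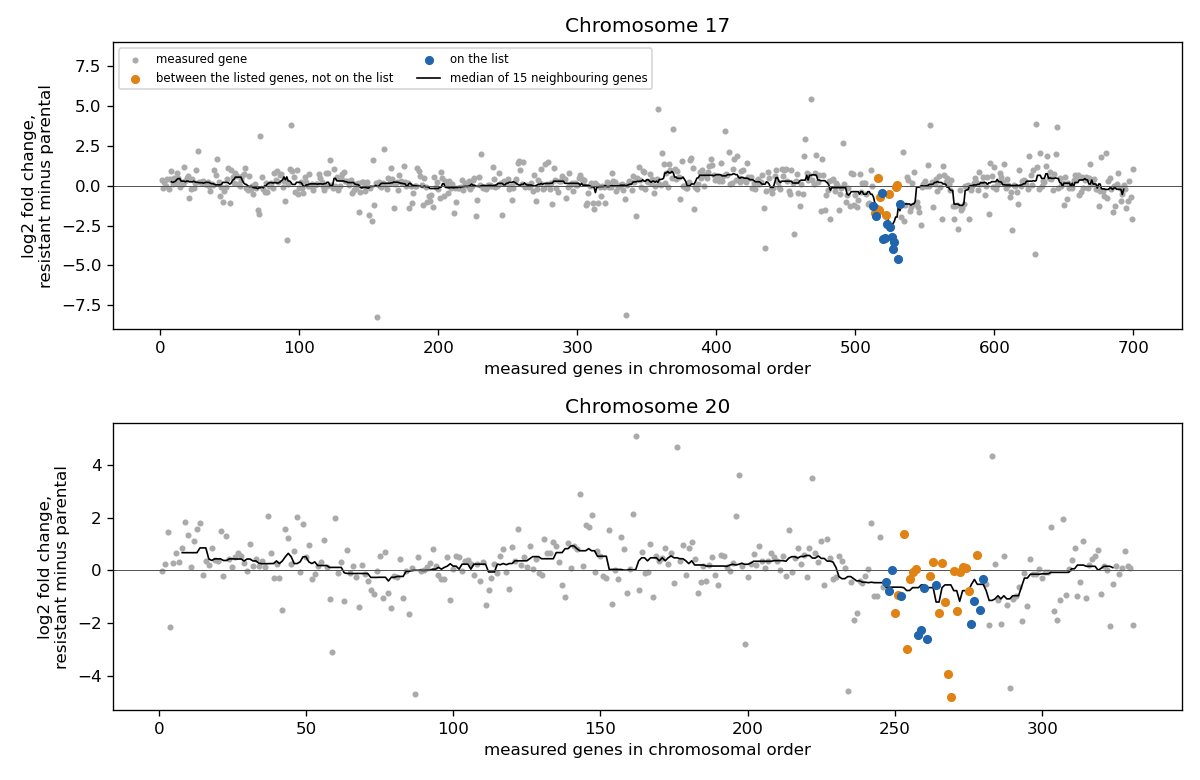
Log2 fold change (vertical axis, resistant minus parental) of measured genes in their order along chromosomes 17 and 20 (horizontal axis, rank), with listed amplified genes in blue, genes between them in orange and the median of 15 neighbouring genes as a line. The listed genes had a median of -2.89 on chromosome 17 and -0.98 on chromosome 20.

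Across the lists, 11 of 28 passed with camera's preset correlation, and none did with an estimated one. The directional fry test, which asks whether a list's genes move one way on balance without reference to other genes, passed for 17 lists. It did not pass for 2 lists that camera called, topoisomerases and p53 targets, and passed for 8 that camera did not call. Of these, pluripotency factors passed downward, and ABC transporters, glutathione metabolism, stem cell markers, fibroblast markers, interferon-stimulated genes, growth factors, and hypoxia and glycolysis passed upward. The mixed fry test, which counts changes in either direction, passed for 27.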

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

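Tests of an intensity-dependent curve, of copy loss and of a lower response to strong genes were chosen before their results were seen, and the others below (compressed range, RNA degradation, parental RNA, Müllerian origin, copy gain at ABCB1, cross-hybridisation) afterwards.

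Probe sets outside the gene comparison also carried signal. Of 2108 probe sets with no gene symbol, 114 were higher and 157 lower in the resistant subline, and of 1043 with several symbols 114 were higher and 144 lower. The 3 probe sets for 18S rRNA were higher on the resistant arrays, by a median of 0.85 log2 units. Within groups their medians also differed, by -0.50 (parental 2 minus parental 1) and 0.39 (resistant 2 minus resistant 1). The group difference in 18S rRNA was not tested.

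Resistant replicate 2 stood apart from resistant replicate 1, with an SD of their difference of 0.550 against 0.190 for the parental pair. An intensity-dependent curve alone is argued against, since the SD was still 0.506 after such a curve was removed (0.189 for the parental pair). RNA degradation is argued against by 3' minus 5' changes of at most 0.050 (ACTB -0.15, GAPDH 0.050). Parental RNA in an amount that lifts 16 genes abundant in parental cells as a set is argued against too. They moved by -0.16 relative to genes low in both, and 6 of the 16 were lower in resistant replicate 2. A trace of parental RNA stays open. Of the most abundant genes, UBB (1.01), KRT19 (0.86) and AGR2 (0.40) were higher in resistant replicate 2 and CDH1 (-0.22) was lower. A compressed signal range may contribute, with the 18 spikes lower by a median of -0.33 and the 27 B. subtilis probe sets higher by 0.23, which met a first criterion, but the parental pair also differed by -0.26 in the spikes, and a stricter criterion, set after seeing this, was not met. Whether compression is a cause therefore cannot be told apart from a difference between the cultures, which was not tested and stays open, since the design text names them with differing amounts in ng of unstated meaning.

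Genes amplified in MCF-7 were lower in the resistant subline. Their median of -1.54 lay below the lowest of 10000 gene sets matched on mean expression over all arrays (-0.80). That mean includes the lowered resistant values, so the matched genes need not be as strong in parental cells. A lower response to strongly expressed genes therefore stays open. Loss of the extra copies is a hypothesis whose test came out as it requires. The 29 unlisted genes lying between the listed ones, all on chromosomes 17 and 20, had a median of -0.34, with 12 lower and 2 higher. That median lay at percentile 0.02 of sets matched in the same way. The sets were drawn without regard to gene order, so the percentile is only a rough guide. The copy loss test cannot separate loss in a subclone from a resistant stock of another origin, and copy number was not measured. For a stock of Müllerian origin, the marker median of 0.083 (SD 1.30 over 21 genes, none on another list, 5 with a parental mean of at least 6) decided nothing, because members went both ways.

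ABCB1 was 192-fold higher. Gain of a segment reaching its measured neighbours is argued against by a median of 0.079 over the 5 measured genes on each side, of which 1 was higher and 3 lower; a gain limited to ABCB1 stays open. Cross-hybridisation from ABCB4 is argued against by that gene's log2 change of 0.31. Selection by doxorubicin, which the design names, stays open and was not tested apart from the subline.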

How the results depend on the processing

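The array weights were the only alternative chosen after seeing the data (1764 higher, 1980 lower). The counts of 1720 higher and 1769 lower genes stayed within 1.5 times under the mean over probe sets, the filter at 6, quantile normalisation, centring, trend and robust options, array weights and a minimum change of 1 (1220 to 1933 higher, 1357 to 1980 lower). The replicate numbers are not stated to pair the cultures. Deviations from the group means correlated at 0.109 between parental 1 and resistant 1, which cannot exclude a shared batch. With the replicate block, 1460 genes were higher and 1572 lower, and 2897 of the calls were kept. Without _s_at and _x_at probe sets there were 924 higher, 1011 lower and 7 lists among 8369 genes, fewer being tested, and 77 of 2303 calls changed sign because another probe set stood for the gene. All probe sets tested separately gave 2781 lower, more being tested, and an adjusted p under 0.01 gave 841 and 688. Leaving out 1 array gave 168 to 4236 higher, 111 to 3360 lower and 7 to 12 lists. By construction, the spread then comes mostly from the wider resistant pair or from the narrower parental pair. An estimated correlation called 0 lists, directional fry 17 and mixed fry 27. These results turned, none of them passing the test in that setting, and the cause was not tested. With the mean over probe sets, BCL2 was -0.22 and the proliferation list -0.055. Without _s_at and _x_at probe sets, GDF15 was 0.16, HES1 0.13, the topoisomerase list 0.040 and the ribosomal list 0.00080. The probe sets then standing for GDF15 and HES1 read low in both groups, so they cannot decide. With the filter at 6, the Wnt list was -0.63 and the Müllerian list -0.022. After quantile normalisation, ALDH1A1 was -0.030 and the ribosomal list 0.016. After centring, ALDH1A1 was -0.074, stem cell markers -0.018, pluripotency -0.032, Müllerian -0.013 and proliferation -0.094. Over the arrays left out, the ranges were -0.042 to 0.086 for ALDH1A1 log2 fold change, -0.11 to 0.36 for BCL2 log2 fold change, -0.075 to 0.15 for proliferation genes, -0.051 to 0.010 for ribosomal protein genes, -0.11 to 0.16 for glutathione and xenobiotic metabolism, -0.030 to 0.16 for breast cancer stem cell markers, -0.0044 to 0.46 for the Hedgehog pathway, -0.053 to 0.23 for Müllerian markers and -0.023 to 0.34 for haematopoietic markers. The ACTB 3' minus 5' difference ran from -0.91 to -0.76. Without detection calls, values near the low end limit folds.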

Other observations

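The families and blocks below were singled out after their values were seen, while the test of gene order was chosen before its result. Among 213 groups of at least 8 genes sharing a symbol stem, 3 passed camera's test. Metallothioneins, which bind metal ions, were higher in 7 of 10 genes (median 1.94, adjusted p = 0.00592). Beta-tubulins, subunits of microtubules, were higher in 7 of 9 (median 1.28, adjusted p = 0.00592), and pregnancy-specific glycoproteins in 6 of 9 (median 1.81, adjusted p = 0.0194). None passed with an estimated correlation, and near-identical members share probes, so the number of genes behind each change is uncertain.

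Genes next to each other changed together. Of 11610 windows of 15 neighbouring genes, 11 had medians below the lowest of 1000 shuffled orders (-1.94), which argues against a chance order, and none lay above the highest (2.20). They formed a block of 18 genes on chromosome 16 from CFDP1 to PLCG2, with 13 lower and none higher, and a block of 21 genes on chromosome 17 from SMG8 to ACE, with 13 lower and 1 higher. The second overlaps the genes amplified in MCF-7.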
